A study of Homo sapiens and Escherichia coli BL21(DE3) with 16 samples.

How the data were processed

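The series holds 16 samples in 8 groups of 2 replicates. Of these, 4 are PAR-CLIP libraries of human HEK293 T-REx Flp-In cells, an embryonic-kidney-derived line that carries a single site for inserting a doxycycline-inducible transgene. The cells were given doxycycline at 2 µg per ml, and the RNA was that crosslinked to FLAG-HA-tagged PKM2, an isoform of the glycolytic enzyme pyruvate kinase. In PAR-CLIP a photoreactive nucleoside in RNA is crosslinked to protein by light, and the crosslinked base is then read as a T-to-C change. Per the labels' protocols, the cytoplasm was taken up in a mild hypotonic detergent buffer, and the washed nuclear pellet was lysed and sonicated. The other 12 samples, 8 of RNA-seq and 4 of an in vitro binding assay with random RNA of 29 nt, were not analysed here.

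The analysis used 1 deposited cluster list per fraction, in which the authors had combined both replicates. Each fraction was therefore treated as 1 pooled sample. Per the labels, the replicates of a fraction shared 1 3' adapter and the fractions used different ones. The values deposited per cluster were counts: the authors gave the number of reads, of distinct reads, of reads with a T-to-C change, with another change or with none, and of conversion and non-conversion events. Reads without, with other and with T-to-C changes summed to the read number in 99.8% of nuclear and 99.4% of cytoplasmic clusters. The authors also deposited a fraction of reads with a T-to-C change (equal to the ratio of the read counts in nearly all clusters) and an end-G fraction. The authors' other deposited columns, such as their scores per cluster, were not used. Cluster caller, aligner and filters are not given in the sources used here. The submitters' processing notes name the genome build hg38 and, with no role, bcl2fastq 2.20.0, Cufflinks 2.2.1 and Cuffdiff. Every cluster in the lists held at least 5 reads, 2 conversion locations and 4 reads with a T-to-C change.

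Transcript classes and gene names were the authors' own annotation. Protein-coding and long-noncoding introns were counted together as introns, start and stop codons with coding sequence, and classes spanning an exon and an intron as boundaries. tRNA genes were found by overlap of at least 1 nt with tRNA genes of the NCBI RefSeq gene table (GRCh38.p14, the assembly of hg38), on either strand, since that table gives none. Of the nuclear clusters whose gene name was in that table, 97.7% lay inside that gene's span, as did 96.7% of the cytoplasmic ones. Coordinates are those of the authors' lists, with both end bases counted.

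Shares of clusters carry 95% Wilson intervals, shares with the motif exact Clopper-Pearson intervals, and differences between shares Newcombe intervals. Mean base contents carry bootstrap intervals over clusters (10000 resamples). All intervals cover counting error only, because amplified reads are not independent molecules and the replicates were pooled. No p-value was computed between the fractions. A G-quadruplex motif was defined as 4 runs of 2 or more G with loops of 1 to 7 nt of any base inside the cluster sequence. Loops could hold G, so a long unbroken stretch of G could count as several runs. Its share was set against 1000 shuffles of each sequence that keep all dinucleotide counts and both end bases, with a one-sided permutation p whose smallest value is 0.001. That p describes 1 list, since clusters are not biological replicates. For 5-mers, the number of clusters holding each was set against the mean of 200 such shuffles, among 5-mers in at least 2% of clusters. Clusters overlapped where they shared at least 1 nt on the same strand.

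Named genes followed a rule fixed before the data were examined, as were the comparisons over whole lists, the gene lists and all but 2 of the alternatives below. The sources of RNA, the G-poor and G-rich classes, the motif by region, the read shares without single sources, glycolysis without PKM and the explanations weighed were added after seeing the data, apart from the comparison of ERC1 with other genes. The rule took the 12 genes with the most reads and the 10 with the most clusters in each list, the 10 nuclear and 5 cytoplasmic motif clusters with the most reads, PKM, and up to 4 members with the most reads of each of 17 gene lists. Genes named outside it are marked in the text, and some genes that it selects are not reported here. For each list, the nuclear share of its clusters was placed among 10000 random lists of the same size drawn from the 2605 genes with a cluster and matched on reads in 10 bins. The percentile is a description with no p-value.

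The motif and 5-mer code was tested on simulated data drawn from the lists' own compositions. With no motif planted in 4649 nuclear-like sequences the fold over shuffles was 0.972 (permutation p 0.910), and with 200 planted it was 1.14 (permutation p 0.005). In 719 cytoplasmic-like sequences the folds were 1.21 (permutation p 0.139) and 3.62 (permutation p 0.005). A planted 5-mer ranked 15 in the nuclear-like and 5 in the cytoplasmic-like set, so a 5-mer of that frequency can miss the first 10 in the nuclear list.

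Alternatives were a minimum of 20 reads per cluster, weighting by reads, 1 cluster per gene, intronic clusters only, runs of 3 or more G, loops to 12 nt, mononucleotide shuffles, medians over clusters, overlapping clusters only, and an overlap of 50% of the shorter cluster. Clusters without tRNA genes and the mitochondrial genome, and 3' UTR clusters only, were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.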

Results

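PAR-CLIP of tagged PKM2 gave 1 combined list of RNA-contact clusters for the nucleus and 1 for the cytoplasm of the HEK293 T-REx Flp-In line, each made from 2 replicates. The nuclear list held 4649 clusters with 189610 reads, and the cytoplasmic list 719 clusters with 160250 reads. The median cluster had 21 reads in the nuclear and 55 in the cytoplasmic list, with 4 and 6 distinct reads. Median length was 25 nt in both. Because the replicates were pooled, no spread between replicates could be had, and differences between the fractions are given with counting intervals only. The fractions also differed in the 3' adapter of their libraries.

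The first question was where PKM2 touches RNA in each compartment, since the series concerns binding to pre-mRNA. Nuclear clusters lay mostly in introns, which are removed from pre-mRNA by splicing, and cytoplasmic clusters lay mostly in 3' untranslated regions, coding sequence and unannotated loci. Introns held 2799 nuclear clusters, 60.2% (95% interval 58.8 to 61.6), and 73 cytoplasmic clusters, 10.2% (8.15 to 12.6), a difference of 50.1 percentage points (47.2 to 52.5). The 3' untranslated regions held 12.4% of nuclear and 34.8% of cytoplasmic clusters, and coding sequence 5.92% and 21.0%. Clusters in 5' untranslated regions made up 1.76% and 3.76%. Exons of noncoding RNAs took similar shares, 6.07% in the nuclear and 4.87% in the cytoplasmic list, and the interval of that difference spanned 0 (-0.741 to 2.73 points). Small and ribosomal RNAs held 1.79% and 5.70%, and unannotated loci 10.2% and 18.9%. Weighted by reads, introns held 44.4% of the nuclear and 8.80% of the cytoplasmic signal, or 4.82% without a single cytoplasmic cluster in RSPH14. By reads the order turned around for coding sequence (10.3% and 5.43%) and for small and ribosomal RNAs (9.15% and 8.16%), but not without the mitochondrial genome (3.59% and 5.21%, and 6.63% and 7.64%). The cytoplasmic share of small and ribosomal RNAs was 4.05% without the largest cluster, in the vault RNA gene VTRNA1-2. The order turned around for noncoding exons too (10.1% and 18.3%), but not without the largest cluster of each list, on a serine tRNA gene (8.34% and 4.12%). The 3' untranslated regions were nearly level by reads (10.0% and 11%). So were the 5' untranslated regions (1.32% and 1.26%), where the order turned around by a small margin, also without the mitochondrial genome (1.54% and 1.27%). These shares include tRNA genes, with 4.81% of nuclear and 60.4% of cytoplasmic reads, which lower the cytoplasmic shares of other regions more. Outside tRNA genes and the mitochondrial genome the lists held 154055 and 61828 reads. Against these stood 19038 and 17626 reads in 3' untranslated regions, and 2508 and 2020 in 5' untranslated regions. Level shares of all reads therefore do not mean level shares outside tRNA, which were not computed by region.

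**Figure D1:**
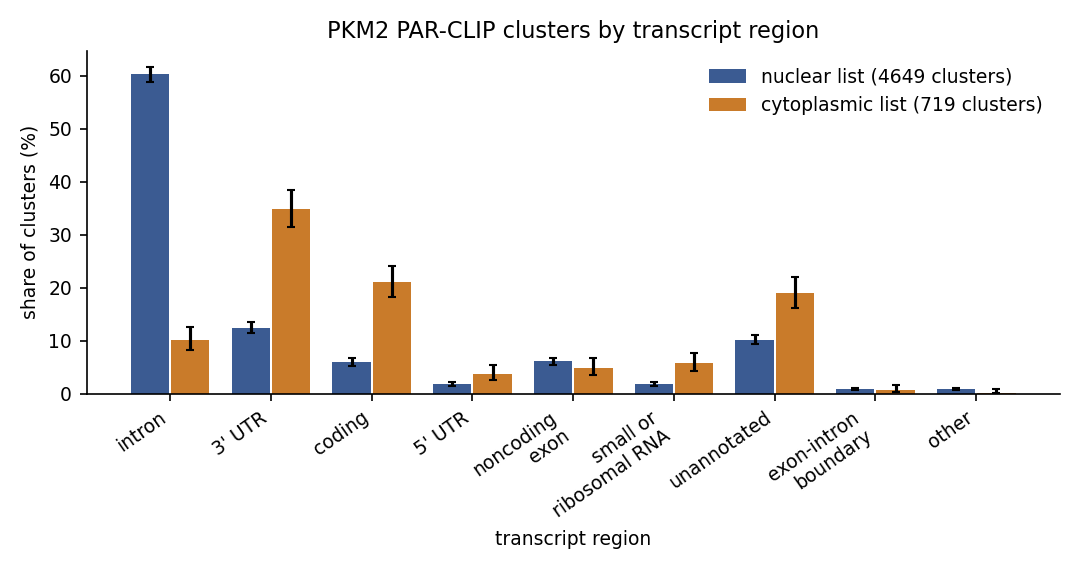
Share of clusters (%, vertical axis) in each transcript region of the authors' annotation, for the nuclear (blue) and cytoplasmic (orange) list, with 95% Wilson intervals as bars. Introns hold 60.2% of nuclear and 10.2% of cytoplasmic clusters, and 3' untranslated regions 12.4% and 34.8%.

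Transfer RNAs took most cytoplasmic reads and mitochondrial RNA a larger share of nuclear reads. Clusters on nuclear-encoded tRNA genes held 60.4% of cytoplasmic reads (118 clusters on 105 genes) and 4.81% of nuclear reads (35 clusters). Mitochondrial clusters held 13.9% of nuclear reads (123 clusters) and 1.07% of cytoplasmic reads (16 clusters). Mitochondria lie outside the nucleus, so the nuclear list also holds RNA from outside it. How pure the fractions were was not measured here. The largest cytoplasmic cluster, with 23748 reads, carried the authors' gene name RP11-867G23.8 and lay at position 66348153 to 66348207 on the plus strand of chromosome 11, where it covered a serine tRNA gene (TRS-GCT3-1). The same gene name led the nuclear list by reads in a single cluster, with 3637 reads. The next cytoplasmic clusters covered the serine tRNA genes TRS-CGA4-1 on chromosome 12 (20172 reads) and TRS-AGA3-1 on chromosome 6 (9766 reads). tRNA genes exist in near-identical copies, so the copy a read came from is uncertain. Intervals of these read shares are narrow (60.1 to 60.6% for cytoplasmic tRNA), but 1 cluster can hold many amplified copies of few molecules.

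**Figure D2:**
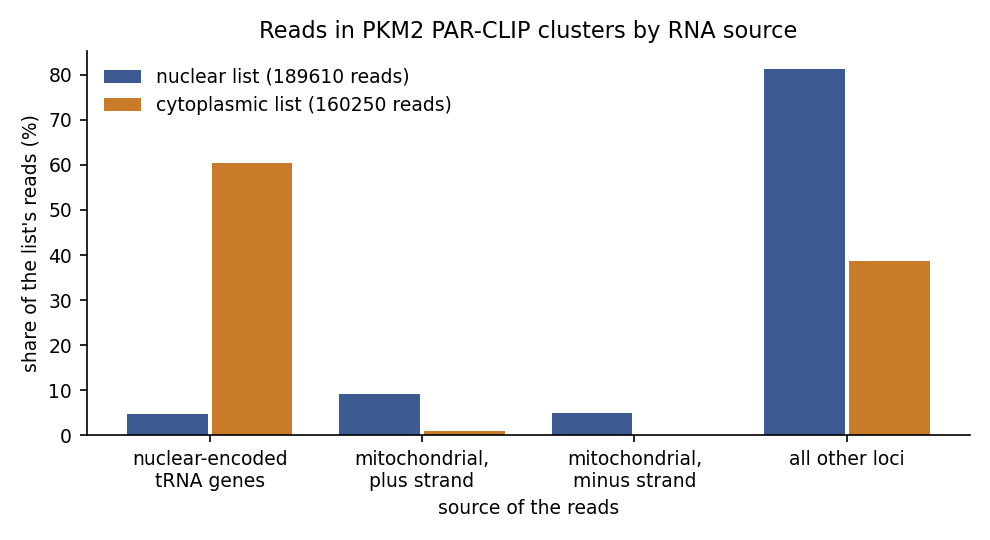
Share of each list's reads (%, vertical axis) by RNA source, for the nuclear (blue) and cytoplasmic (orange) list. Nuclear-encoded tRNA genes hold 60.4% of cytoplasmic and 4.81% of nuclear reads, and the 2 mitochondrial strands together 13.9% of nuclear reads.

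The lists shared few sites. Only 96 cytoplasmic clusters (13.4%, 11.1 to 16.0) overlapped a nuclear cluster, and 93 nuclear clusters (2.00%, 1.64 to 2.44) overlapped a cytoplasmic one. Of the overlapping cytoplasmic clusters, 26 lay on tRNA genes. At the level of genes, 210 of the 451 genes in the cytoplasmic list also had a nuclear cluster, 46.6% (42.0 to 51.2), whereas the nuclear list named 2364 genes. With at least 20 reads per cluster, 131 genes were shared, and the nuclear list fell to 2430 clusters.

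Nuclear clusters were richer in G and poorer in A and C than cytoplasmic clusters. Mean G content was 24.5% (23.9 to 25) in the nuclear and 18.2% (17.2 to 19.2) in the cytoplasmic list, a difference of 6.27 points (5.13 to 7.39). A was 19.1% and 23.2%, and C 20.8% and 24.8%. T was 35.6% and 33.8%, but this order turned around among intronic clusters (-1.29 points) and among 3' UTR clusters (-2.29 points). The intronic clusters differed more in G (10.4 points) and A (-7.25 points) than all clusters. The C difference was smaller among intronic (-1.90 points) and 3' UTR clusters (-1.45 points).

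Over all clusters the lists held similar shares of G-poor clusters and differed in the G-rich ones. Clusters with under 10% G made up 36.6% of the nuclear and 38.8% of the cytoplasmic list, clusters with 10 to 40% G 34.5% and 54.9%, and clusters with 40% G or more 28.9% and 6.26%. Within regions the G-poor shares differed as well, at 36.7% nuclear and 54.8% cytoplasmic in introns, 47.1% and 61.6% in 3' untranslated regions, and 48.4% and 32.5% in coding sequence. The 1344 G-rich nuclear clusters averaged 49.6% G, and 67.5% of them were intronic. The 1702 G-poor nuclear clusters averaged 44.7% T and 27.3% C, and 60.4% of them were intronic. G was the last base in 74.0% of nuclear (72.8 to 75.3) and 87.9% of cytoplasmic clusters (85.3 to 90.2), and the first base in 2.11% and 4.87%.

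**Figure D3:**
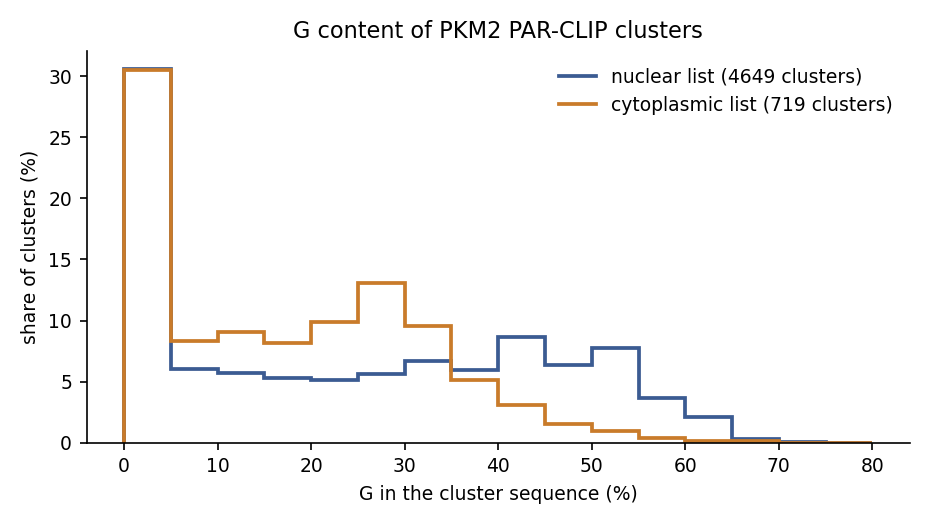
Share of clusters (%, vertical axis) by the G content of their sequence (%, horizontal axis, in steps of 5) for the nuclear (blue) and cytoplasmic (orange) list. Both lists peak under 5% G, and the nuclear list also holds 28.9% of its clusters at 40% G or more, against 6.26% in the cytoplasmic list.

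The next question was whether the clusters hold sequences able to form G-quadruplexes, stacks of guanine quartets. Such motifs were more frequent in nuclear than in cytoplasmic clusters, and in the nuclear list more frequent than in shuffled sequences. As defined here, a long stretch of G can count as several runs, so the motif need not hold separate stretches. The motif stood in 987 of 4649 nuclear clusters, 21.2% (exact interval 20.1 to 22.4), and in 27 of 719 cytoplasmic clusters, 3.76% (2.49 to 5.42). The difference was 17.5 points (15.5 to 19.1), and 1.58 points when runs of 3 or more G were required. Shuffling the nuclear sequences left 16.8% with a motif, so the observed share was 1.26-fold higher (one-sided permutation p 0.001, the smallest the shuffles can give). Shuffled cytoplasmic sequences gave 3.19%, a fold of 1.18 (one-sided permutation p 0.161). That result passed 0.05 with loops to 12 nt (fold 1.25, permutation p 0.0120) and with mononucleotide shuffles (fold 1.33, permutation p 0.0410). Whether the folds of the lists differ was not tested.

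By region, nuclear introns had the motif in 663 of 2799 clusters, 23.7%, against 18.8% after shuffling (fold 1.26, permutation p 0.001). Nuclear 3' untranslated regions had it in 18.7% (fold 1.29, permutation p 0.001), noncoding exons in 17.7% (fold 1.37, permutation p 0.001) and unannotated loci in 23.0% (fold 1.23, permutation p 0.001). In nuclear coding sequence 15 of 275 clusters held it, 5.45% (fold 1.33, permutation p 0.0739), and in 5' untranslated regions 21 of 82, 25.6% (fold 1.07, permutation p 0.373). These p-values, computed region by region, were not adjusted. The cytoplasmic list held it in 3 of 73 intronic, 11 of 250 3' UTR and 2 of 151 coding clusters. Within 3' untranslated regions alone the nuclear share was 14.3 points higher (9.84 to 18.2).

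**Figure D4:**
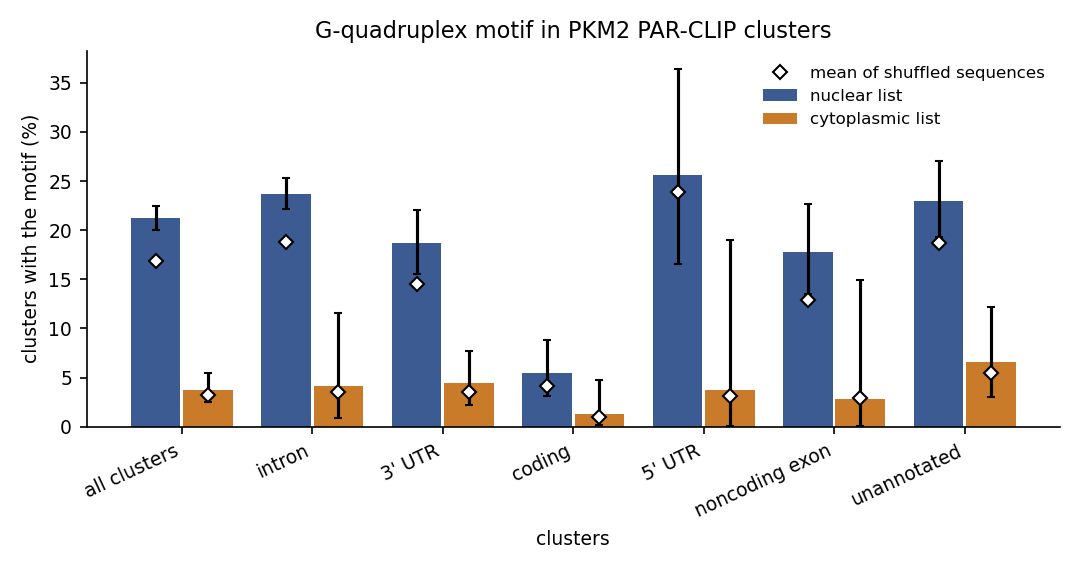
Share of clusters with a G-quadruplex motif (%, vertical axis) by region, for the nuclear (blue) and cytoplasmic (orange) list, with exact 95% intervals as bars and the mean share after dinucleotide shuffling as diamonds. Over all clusters the nuclear share is 21.2% against 16.8% after shuffling, and the cytoplasmic share 3.76% against 3.19%.

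The motif clusters with the most nuclear reads came from mitochondrial RNA, XIST, and introns or a 3' UTR of protein-coding genes. The first lay in MT-ND6, a complex I subunit encoded on the minus strand of the mitochondrial genome, at 14454 to 14577 (2842 reads). Minus-strand mitochondrial clusters without a gene name followed at 314 to 403 (1510 reads), 10929 to 10972 (310 reads) and 13746 to 13790 (240 reads). XIST, the long noncoding RNA that coats the inactive X chromosome, had an exonic motif cluster on the minus strand of chromosome X at 73842027 to 73842078 (400 reads). An intron of SRRM2, a spliceosome scaffold, held AATAGGGGGGGTGGTGGTTTGTTCG on the plus strand of chromosome 16 at 2759906 to 2759930 (378 reads). An intron of ANKRD11, a chromatin regulator, held TTCCGGTGGGGTGGGGGGTGGATTG on the minus strand of chromosome 16 at 89287736 to 89287760 (256 reads). The 3' UTR of PRMT1, an arginine methyltransferase, had a cluster of 233 reads on chromosome 19 at 49688342 to 49688383. An intron of HNRNPH1, an RNA-binding splicing regulator, had one of 230 reads on chromosome 5 at 179617369 to 179617402.

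Among the 27 cytoplasmic motif clusters, 8 lay on tRNA genes, and these held most of the leading places by reads. Of the 5 with the most reads, 4 lay on tRNA genes for glycine (TRG-TCC3-1, 604 reads), glutamate (TRE-CTC1-7, 365 reads), leucine (TRL-TAG1-1, 254 reads) and tyrosine (TRY-GTA3-1, 248 reads). The other was TTCGGGGGGGTGGGGGGCTTG in the 3' UTR of FOXC1, a forkhead transcription factor, on the plus strand of chromosome 6 at 1613727 to 1613747 (387 reads).

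Enriched 5-mers differed between the lists. In the nuclear list all of the first 10 were G-rich: GGCGG (211 clusters, log2 ratio over shuffles 1.14), GAGGA (1.04), GGAGG (634 clusters, 1.02), AGGGA (1.01), GGGCG (0.97), GAGGT (0.97), GGGAG (0.92), TGGGA (0.89), AGGGT (0.86) and GCGGG (0.81). In the cytoplasmic list TTCGA (28 clusters, 1.96), GTTCG (40 clusters, 1.67) and GGTTC (49 clusters, 1.28) came first, the bases of the conserved tRNA T loop, followed by GGTTA (1.27), TCGAA (1.25), GTGGT (1.23), AGTGG (33 clusters), CGGAG (1.14), AGAGC (1.14) and GGCGC (1.10). Without tRNA and mitochondrial clusters only 2 of these 10 stayed among the first 10, and mononucleotide shuffles kept 1 of the nuclear and 3 of the cytoplasmic 10.

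By named gene, the nuclear list was led by XIST, with 117 clusters and 10734 reads (5 with the motif), and it had 15 clusters and 1106 reads in the cytoplasmic list. ERC1, a presynaptic and cell-cortex scaffold, followed by clusters with 43 nuclear (2519 reads) and 11 cytoplasmic (1701 reads), all of them intronic. NEAT1, the RNA scaffold of paraspeckles, had 28 nuclear clusters and SRRM2 27, of which 19 were intronic. ANKRD11 had 21 nuclear clusters, all intronic and 10 with the motif, and none in the cytoplasmic list. ZNF146 had 17, DAZAP1 14, EIF4G3 13, HNRNPH1 12 and MT-ND5 12 nuclear clusters. By reads, MT-RNR1 (3705), MT-ND6 (2934), MT-RNR2 (2515), MT-ND4 (2165), the minor spliceosomal RNA RNU11 (1986), MT-ND5 (1940), the signal recognition particle pseudogene RN7SL634P (1527) and the spliceosomal RNA RNU4-2 (1480) ranked among the nuclear genes. Only 8.38% of the RN7SL634P reads carried a T-to-C change, against 79.3% over the nuclear list. Multicopy small RNAs and their pseudogenes share sequence, so these assignments are uncertain.

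All ERC1 clusters of the nuclear list lay on the plus strand from position 1200851 of chromosome 12 onwards, although the gene runs from 989959 to 1495933. The first 10 kb from there held 13 nuclear clusters with 1224 reads and 10 of the 11 cytoplasmic clusters with 1687 reads. The remaining cytoplasmic cluster began at 1141460. The line carries an inserted transgene whose position is not given in the sources used here, so RNA transcribed from an insertion or another start inside the gene is not separated from ERC1 pre-mRNA.

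**Figure D5:**
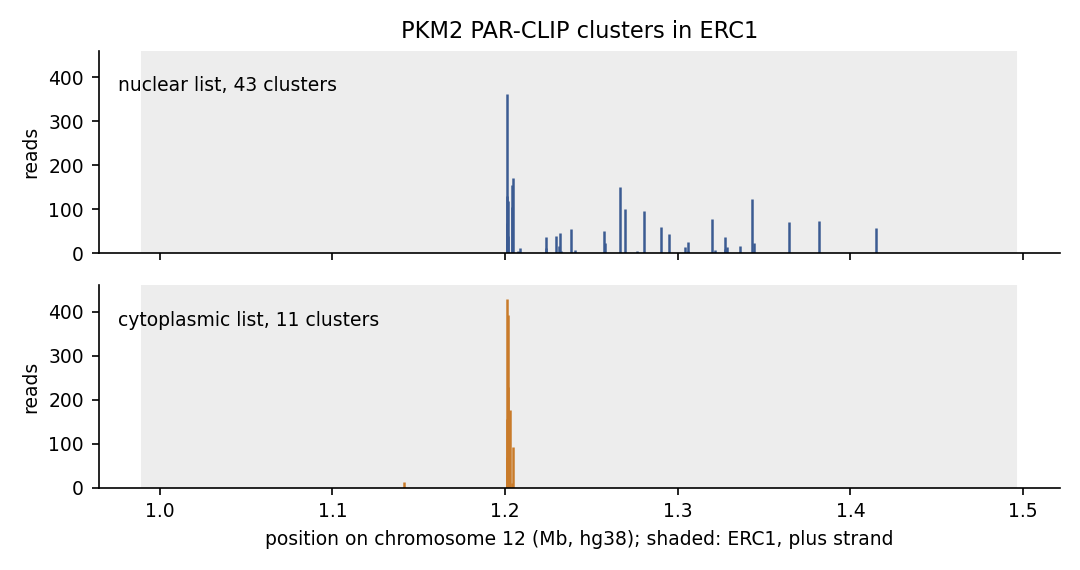
Reads per cluster (vertical axis, linear) along ERC1 on chromosome 12 (Mb, hg38, horizontal axis; shaded, the gene from 989959 to 1495933), with the 43 nuclear clusters above and the 11 cytoplasmic clusters below. No nuclear cluster lies before 1200851, and 10 of 11 cytoplasmic clusters lie within 10 kb of that position.

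In the cytoplasmic list VTRNA1-2, a vault RNA, had 6861 reads in 1 cluster, against 754 nuclear reads in 2. A single intronic cluster in RSPH14 had 6701 reads, of which 12.5% carried a T-to-C change, against 66.9% of reads over the whole list. An unnamed cluster on chromosome 4 (73724265 to 73724286) had a near-identical sequence and 2352 reads, 99.9% of them with a T-to-C change. The assignment of these reads to an RSPH14 intron is therefore uncertain. RPPH1, the RNA of ribonuclease P, had 1801 cytoplasmic and 84 nuclear reads, and VTRNA1-1 652 and 40. RP11-473M20.16 had 958 reads in a cluster on a lysine tRNA gene (TRK-CTT3-1). EEF2, the translocation factor of translation, had 8 cytoplasmic clusters (847 reads) and 4 nuclear (118 reads). HNRNPA2B1 had 3 cytoplasmic (681 reads) and 11 nuclear (697 reads), FOXC1 3 cytoplasmic (673 reads) and none nuclear, NUCKS1 5 and 3, SON 4 and 11, ARF1 4 and 5, and CDK1, the mitotic kinase, 3 cytoplasmic (324 reads) and none nuclear.

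PKM itself, the gene of the tagged protein, had 4 cytoplasmic clusters with 412 reads, all in the authors' coding classes and none with the motif. Of these, 1 was classed as stop codon although it lay upstream of the other 3, so that class may come from another transcript of the gene, which was not checked. The nuclear list held 1 PKM cluster, of 7 reads, on chromosome 15 (72218962 to 72218997). The authors classed it as running from coding sequence into intron, and the transcript behind that class was not checked. The largest cytoplasmic PKM cluster lay at 72208709 to 72208744 with 143 reads. The lists cannot separate RNA of the endogenous gene from that of the inserted transgene.

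The gene lists were compared by the nuclear share of their clusters, which was 87.7% over all genes. Of the 17 lists, 4 fell under the 2.5th percentile of random lists and 0 above the matching upper bound. The 4 were ribosomal proteins, translation factors, small structured RNAs and replication-dependent histones, all with a lower nuclear share of clusters than random lists. Those were matched on reads, not on gene length or introns, and introns held 60.2% of all nuclear clusters. Of the nuclear clusters of small structured RNAs and histones, 0 were intronic. A low share in genes with short or no introns is therefore not separated from a difference in binding. Lists whose clusters were all nuclear had percentiles of 74.3 to 94.8, because random lists were often all nuclear too. For these lists the upper bound was out of reach. Ribosomal protein genes had 23 nuclear and 15 cytoplasmic clusters in 22 of 36 members, a nuclear share of 60.5% (percentile 0.04). Examples were RPS4X (3 nuclear, 2 cytoplasmic), RPL23 (1 and 2), RPL15 (0 and 2) and RPS23 (0 and 2). Translation factors had 26 and 18 clusters in 15 of 22 members, 59.1% (percentile 0.265), with EEF2, EIF4G2 (24 nuclear and 138 cytoplasmic reads), EIF3B (83 and 56) and EIF4A1 (118 and 68) carrying the most reads. Small structured RNAs had 11 and 13 clusters in 14 of 20 members, 45.8% (percentile 0.01). Their reads were nearly level, at 4127 nuclear and 4157 cytoplasmic. Histone genes, whose mRNAs lack introns and poly(A) tails, had 3 and 9 clusters in 6 of 12 members, 25% (percentile 0.02). HIST1H3B (3 cytoplasmic clusters, 152 reads), HIST1H2BD (2, 46 reads) and HIST2H2AC (1, 53 reads) had no nuclear cluster, and HIST1H1C had 2 nuclear and 1 cytoplasmic.

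Metabolic genes did not pass those bounds. Glycolysis genes had 18 nuclear and 11 cytoplasmic clusters in 9 of 20 members, a nuclear share of 62.1% (exact interval 42.3 to 79.3, percentile 2.84), and 16 of the 18 nuclear clusters were intronic and 8 held the motif. PKM, the gene of the transgene, gave 4 of the 11 cytoplasmic clusters and 412 of the 609 cytoplasmic reads, and without it the nuclear share was 70.8% (48.9 to 87.4). PFKL, the liver-type phosphofructokinase, had 6 nuclear clusters, 4 with the motif, and 1 cytoplasmic. PFKP, its platelet-type relative, had 4 nuclear clusters and none cytoplasmic, and LDHB, a lactate dehydrogenase subunit, 1 in each. Genes of the pentose phosphate, serine and one-carbon pathways had 15 nuclear and 5 cytoplasmic clusters in 9 of 15 members (75%, percentile 13.8), with MTHFD2 (141 nuclear and 199 cytoplasmic reads), PSAT1 (32 and 177), SHMT2 (76 and 36) and TYMS (0 and 37) leading by reads. None of their clusters held the motif.

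Genes listed as nuclear partners and targets of PKM2 had 7 nuclear and 0 cytoplasmic clusters in 5 of 16 members (percentile 74.3). Whether each member, JMJD8 among them, is such a partner or target was not checked here. Those with the most reads were VEGFA (62 reads), JMJD8 (44 reads), EP300 (32 reads) and NFE2L2 (32 reads in 2 clusters), and all but EP300 had 1 cluster with the motif. Genes with described G-quadruplexes also had 7 and 0 in 6 of 18 members (percentile 74.7), among them VEGFA again, NRAS (21 reads, with the motif), BCL2 (25 reads) and TERF2 (2 clusters, 31 reads). Counts this small bound the nuclear share only to 59.0% or more in either list.

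RNA-binding protein genes had many clusters without standing apart from other genes. Splicing factors and hnRNPs had 108 nuclear and 19 cytoplasmic clusters in 25 of 29 members (85%, percentile 57.4), and 24 of the nuclear ones held the motif and none of the cytoplasmic. SRRM2, SON, HNRNPC (10 nuclear, 1 cytoplasmic) and SRSF3 (2 and 2) had the most reads. Genes for G-quadruplex-binding proteins and helicases had 76 and 17 clusters in 17 of 27 members (81.7%, percentile 39.3), including HNRNPA2B1, HNRNPH1 and DDX17 (7 and 2).

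The list named nuclear long noncoding RNAs had 48 nuclear and 2 cytoplasmic clusters in 6 of 16 members (96.0%, percentile 92.9). Whether each member is mainly nuclear was not checked. NEAT1 gave 28 and MALAT1 12 of the 48. LINC00657 (NORAD), named here outside the rule, had 0 nuclear clusters and 1 cytoplasmic. NEAT1 (1248 reads), MALAT1 (12 clusters, 571 reads) and GAS5 (3 clusters, 408 reads) had none in the cytoplasmic list, and LRRC75A-AS1 had 3 and 1. All 3 GAS5 clusters were intronic, so they need not come from the mature GAS5 RNA. In the largest, of 200 reads, 12% of reads carried a T-to-C change, against 79.3% over the nuclear list. Mitochondrially encoded genes had 85 and 12 clusters in 14 of 15 members (87.6%, percentile 77.7). Chromatin and transcription genes had 41 and 3 in 19 of 25 members (93.2%, percentile 79.3), including MED13 (258 nuclear reads), TRRAP (193) and CREBBP (68). Long neuronal-type genes had 16 and 0 in 7 of 20 members (percentile 87.2), all intronic, among them RBFOX2, FHIT, GPHN and AUTS2. Secretory and membrane mRNAs, expected at the endoplasmic reticulum, had 21 and 0 in 9 of 17 members (percentile 94.8), with APP (7 clusters, 358 reads), CD81 (135 reads), SLC7A5 (95 reads) and SLC3A2 (64 reads). Only 6 of these 21 nuclear clusters were intronic. Chaperone and endoplasmic reticulum stress genes had 7 and 5 in 7 of 19 members (58.3%, percentile 2.71), with HSP90AB1 (500 cytoplasmic reads), CANX, HSP90AA1 and HSP90B1 named. Cytoskeletal genes had 6 and 1 in 4 of 19 members (85.7%, percentile 48.8), namely ACTG1, DYNC1H1, TUBA1B and MAP1B.

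T-to-C conversions, the mark of a crosslink, made up a close share of all conversion and non-conversion events in both lists. The share of converted reads was higher in the nuclear list. T-to-C conversion events were 9.46% (9.41 to 9.50) of all events in the nuclear list, from 149280 conversions, and 9.92% (9.86 to 9.97) in the cytoplasmic list, from 106897. The median over clusters was 11.1% in both. Reads with a T-to-C change made up 79.3% of nuclear and 66.9% of cytoplasmic reads, and all reads were converted in 69.2% and 56.1% of clusters. The event share also counts non-conversion events, so it depends on how many events were counted per read. A close event share therefore does not show equal crosslinking, which was not tested. Every cluster in the lists held reads with a T-to-C change, so these shares do not cover clusters without one.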

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

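Both signals here were looked for only after the lists had been examined. The authors' annotation gave no name to cytoplasmic clusters on tRNA genes that held 67671 reads, 42.2% of all cytoplasmic reads, in 93 clusters on 85 tRNA genes. In the nuclear list, 26 unnamed clusters on tRNA genes held 2.64% of the reads. These clusters are given here because unnamed loci enter none of the gene comparisons.

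Unnamed clusters on the minus strand of the mitochondrial genome held 6018 nuclear reads in 31 clusters, 3.17% of the list, against 217 cytoplasmic reads in 2 clusters. They averaged 30.7% G, and 5 held the G-quadruplex motif, whereas the 88 nuclear clusters on the plus strand averaged 9.69% G and none held it.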

How the results depend on the processing

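Settings without tRNA and mitochondrial clusters and with 3' UTR clusters only were chosen after seeing the data. No paired analysis was possible because the deposited lists pool both replicates of each fraction, so neither a replicate block nor leaving out a replicate was run. Alternatives that need a genome (windows of 25 or 50 nt and flanks) or a second annotation of regions were not run, and a minimum of 2 conversion locations removed no cluster. Over 22 results, 43 of 73 alternative values stayed inside the interval, or within 1.5 times the count, of the value reported, or on its side of the test threshold. With at least 20 reads per cluster the nuclear list held 2430 clusters, 57.1% of them intronic, its conversion share was 9.29%, and 131 genes were in both lists. Weighting by reads gave a nuclear intronic share of 44.4%, 1 cluster per gene 55.4%, and leaving out tRNA and mitochondrial clusters 62.3%, all above the cytoplasmic shares of 8.80% to 11%. The nuclear minus cytoplasmic difference in G stayed positive in all 5 alternatives, at 10.4 points among intronic clusters, 9.0 without tRNA and mitochondrial clusters and 8.73 in 3' UTRs. For A the same 3 settings gave -7.25, -5.17 and -4.99 points. For C, intronic clusters gave -1.90 and 3' UTR clusters -1.45. T reversed among intronic clusters (-1.29) and 3' UTR clusters (-2.29) and fell to 0.143 without tRNA and mitochondrial clusters. The nuclear motif fold lay between 1.06 (loops to 12 nt) and 1.8 (mononucleotide shuffles), with the smallest permutation p in all 7 alternatives. The cytoplasmic fold passed 0.05 with loops to 12 nt (1.25) and mononucleotide shuffles (1.33). The difference in motif share was 1.58 points with runs of 3 or more G, 19.6 among intronic and 14.3 among 3' UTR clusters. Of the 10 named 5-mers, mononucleotide shuffles kept 1 nuclear and 3 cytoplasmic, and leaving out tRNA and mitochondrial clusters kept 2 cytoplasmic. The median over clusters of the conversion share was 11.1% in both lists, and the share of all events in clusters overlapping the other list was 7.68% in the nuclear and 10.4% in the cytoplasmic list. Apart from the mononucleotide shuffles, which hold no dinucleotide counts fixed, and the smaller cluster sets, the cause of each change was not tested.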

Other observations

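The tests in this part were chosen only after seeing the result, except the comparison of ERC1 with other genes, which was set before its result was known. Clusters across the splice sites of coding exons differed by side. Of 16 nuclear clusters running from coding exon into intron, 11 held the G-quadruplex motif (68.8%, exact interval 41.3 to 89.0) and 14 held GGT followed by A or G. Of 13 running from intron into coding exon, 0 held the motif (upper exact limit 24.7%) and 3 held GGT followed by A or G. The 4 nuclear clusters running from a 5' UTR into an intron held 0 motifs. Mean G content was 42.6% in the 16 clusters and 19.5% in the 13, and no shuffles were run by side. The base content of each kind of splice site is therefore not separated from binding by PKM2. Over all 38 nuclear boundary clusters the motif fold over shuffles was 1.34 (one-sided permutation p 0.0659). Among genes picked after seeing their values, HOXB3, a homeobox gene, had 10 nuclear clusters, all intronic and 5 with the motif, and MBD3, a chromatin protein of the NuRD complex, had 8, with 5 motif clusters.

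Small nucleolar RNAs, guides of ribosomal RNA modification, had 42 nuclear and 4 cytoplasmic clusters, 0.903% and 0.556% of the clusters and 2.08% and 0.274% of the reads. Small nuclear RNAs had 11 and 7 clusters, a larger share of cytoplasmic clusters (0.237% and 0.974%) but of nuclear reads (2.15% and 0.821%). The authors' mixed class of other small RNAs had 8 and 15 clusters (1.40% and 5.60% of the reads), and ribosomal RNA 1 and 7 (0.00633% and 0.276% of the reads). Single clusters carried the mixed class. VTRNA1-2 had 6861 of its 8971 cytoplasmic reads, and RN7SL634P 1527 of its 2653 nuclear reads. Of cytoplasmic tRNA reads, serine tRNAs with the anticodons GCT, CGA and AGA took 24.6%, 21.1% and 13.0%, out of 44 tRNA families. The authors' end-G fraction averaged 0.751 on the plus and 0.0212 on the minus strand of the nuclear list, although 71.4% and 77.0% of the sequences on these strands ended in G.

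The motif share was higher in the nuclear list than in the cytoplasmic one. A different mix of transcript regions is argued against as the whole cause, since within 3' UTR clusters alone the difference was 14.3 points (9.84 to 18.2). Dilution by tRNA and mitochondrial clusters would need these to hold the motif less often than other cytoplasmic clusters. The order was the opposite, at 6.78% of tRNA clusters (8 of 118, 2.97 to 12.9) and 3.08% of all other loci (18 of 585, 1.83 to 4.82). Mitochondrial clusters held it in 1 of 16. Without both sources the difference was 18.8 points (16.7 to 20.4), but they were too few for their removal to bring it near 0. Library preparation that differed between the fractions cannot be told apart from the compartment, because the fractions had 0 3' adapter sequences in common. A difference in what nuclear and cytoplasmic PKM2 binds, the comparison the design names, remains open as untested. The lists also differed at the cluster ends, with G last in 74.0% of nuclear (72.8 to 75.3) and 87.9% of cytoplasmic clusters (85.3 to 90.2). The motif was sought only inside the cluster sequence, and whether unequal cutting at G bears on its share was not tested. Carry-over of RNA between the fractions, whose purity was not measured, was not tested as a cause either.

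ERC1 clusters in the nuclear list began 210892 nt into the gene. Whether long stretches without a cluster at the 5' end are common in genes with 10 or more nuclear clusters cannot be told apart from a feature of ERC1. The comparison took 20 other genes that the RefSeq gene table names and that held 10 or more nuclear clusters inside their span. Genes that did not meet this were left out, among them MT-ND5 with 12 nuclear clusters. Of the 20, 5% (1 gene, HNRNPH1, exact interval 0.127 to 24.9%) had a first cluster as far in as a share of gene length, too few to decide. In nt, the longest such stretch in these 20 genes was 20848, and they are shorter than ERC1. Where the transcript bound at ERC1 starts was not tested, and no biological explanation was tested.

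G-poor clusters made up 36.6% of the nuclear list. Whether a nuclease that cuts after G left the G-poor clusters cannot be told from their ends. Of the 1702, 66.7% ended in G (64.5 to 69%), although their mean G content was 3.76%. Of all nuclear clusters 74.0% ended in G, so that end is common to the whole list and does not set the G-poor clusters apart. Such a nuclease would leave G ends over the whole list too, so this does not count against it. No G stood before the last base in 1366 nuclear (29.4%) and 214 cytoplasmic clusters (29.8%), similar shares in both lists. Neither the nuclease nor its amount is given in the sources used here. A preference of PKM2 for G-poor RNA stays open, and no biological explanation was tested.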
